A study of Mus musculus with 8 samples.

How the data were processed

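Phosphorylated CREB1, the activated form of a transcription factor that binds cAMP response elements, was profiled in skeletal muscle of male Balb/c mice by chromatin immunoprecipitation followed by paired-end sequencing (ChIP-seq). Per the labels, C26 mice received a subcutaneous injection of C26 cells, a mouse colon adenocarcinoma line whose tumors cause muscle wasting (cachexia), at 2 months of age, and CTRL mice served as controls. The series held 8 samples: 2 phospho-CREB1 libraries of CTRL muscle, 2 of C26 muscle, and 4 input libraries of sonicated chromatin without immunoprecipitation. Per the labels' protocols, frozen muscle was pulverized, crosslinked in 1% formaldehyde for 15 minutes, quenched with 0.125 M glycine, sonicated to fragments near 0.5 kb, and precipitated with 5 µg of antibody. The extraction protocol allows for an antibody to CREB or to phospho-CREB1 without saying which served these libraries, while the titles and the series design say phospho-CREB1, which is the name used here. The sample labels and the series design name the gastrocnemius as the tissue while the extraction protocol names the quadriceps, so the tissue is called muscle here. The treatment protocol also describes injections of rolipram, a phosphodiesterase 4 inhibitor, or vehicle into C26 mice, and does not say which of these the ChIP-seq mice received.

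Per the submitters' processing notes, the tools were FastQC 0.11.2, Bowtie2 2.3.5.1, Picard, SAMtools 1.6 and MACS2 2.1.4, and the genome build was mm10 (GRCm38). Each of the 4 phospho-CREB1 libraries came with its own peak list, and per the labels each library was set against a numbered input of its own group with a q threshold of 0.05. Peaks were therefore called per library and not on pooled replicates. A further filtering step that the labels name only by an abbreviation is not explained in the sources used here. Each deposited list gives, for every peak, its start, end and summit, the fold enrichment over input at the summit, and the −log10 q-value, both as the authors' peak caller wrote them. The fold enrichment and −log10 q are each peak's own values on a scale set by that library and its input, so they were used only to describe, rank or filter peaks within 1 list. The strength of a peak is its percentile by −log10 q within its own list, with 100 for the strongest. Read counts were not analysed here. The sequencing depth of the libraries is therefore unknown, and a region without a peak is a region that did not pass the authors' threshold in that library, which is not the same as an unbound region.

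Peaks of the 4 lists were merged into regions wherever they overlapped by at least 1 bp, and a region counted as present in each library with a peak in it. A region was called reproducible in a group when both libraries of the group had a peak in it, CTRL-only when both CTRL libraries and neither C26 library had one, and C26-only for the reverse. Gene positions came from a table of the GRCm38.p6 annotation, the same build as the peaks, which gives the span of each gene without its strand, transcript starts or exons. The design fixed before the data were examined called for promoter peaks within 1000 bp of a transcription start. Because strand was not given, a gene-end peak was used in its place. Its summit lay within 1000 bp of either end of the span of 1 of 21883 protein-coding genes on 21 chromosomes. A region was near a gene end when any of its peaks, from any library, had its summit within 1000 bp of one. The 2 kinds of end were compared in 7314 isolated genes longer than 10000 bp and at least 5000 bp from other genes. An estimated 2.27% to 3.06% of their end peaks lay at the less frequent of the 2 gene ends. The estimate takes peaks at the 2 ends of a gene as independent, which was not tested. Under it, nearly all end peaks of these genes sat at 1 kind of end. A search for the cAMP response element and a split into exons and introns were planned and were not run, because no genome sequence or exon annotation was used here.

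With 2 libraries per group there are 6 assignments of the libraries to the groups, and the smallest two-sided exact permutation p is 0.333. Group differences in peak number, covered length, width and location are therefore given as values with each library beside them. Counts of regions and genes were compared with the counts from the other splits of the 4 libraries into pairs, 3 splits in all. Shares of peaks, regions and genes carry 95% Wilson intervals, which cover counting error only. Overlap was set against random placement of the C26 peaks within their chromosomes (100 shuffles), avoiding the first 3000000 bp of each chromosome. In all, 19 gene lists covering mitochondrial, ribosomal, CREB1, atrophy, contractile and clock genes and markers of other cell types were fixed before the data were examined. For each list, the share of genes with a gene-end peak in both CTRL libraries was compared with all other protein-coding genes by a two-sided Fisher's exact test. Among genes with such a peak, the share that was CTRL-only was compared in the same way, with Benjamini-Hochberg adjustment over the lists in each family. These tests run over genes, which are not replicates, and describe these 4 libraries. An exact Mantel-Haenszel test over deciles or 3 bins of the lower of the 2 CTRL percentiles compared groups of regions or genes of like peak strength.

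Genes were named by a rule fixed before the data were examined: the 10 CTRL-only genes with the strongest CTRL peaks (by the lower percentile), the 6 C26-only genes, the 6 strongest genes with a peak in all 4 libraries, up to 3 CTRL-only members of each list, and Creb1, Crem, Ppargc1a, Nr4a1, Nr4a3, Sik1, Per1 and Fos whatever their values. Other genes given as examples of a list, and all regions away from gene ends, were chosen after their values were seen. Some genes that the rule or a list count would name are not reported here. The replicate numbers are shared between the groups in the labels, and nothing in the labels ties a numbered CTRL library to the C26 library of the same number. The labels also do not say whether replicates came from separate animals, so the spread between replicates may be partly technical.

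The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The merging was tested on simulated data with 2000 planted sites, of which 1960 received a peak, and 100% of these were found with the right presence pattern. Peaks planted at the same site always overlapped and those of neighboring sites could not. The simulation therefore checks the code and not how close or partly overlapping peaks were merged. The list test was tested on 7035 genes with planted effects in 200 simulations per list: an odds ratio of 4 was called in 84% of simulations for the complex I list, 44% for the sarcomere list and 21.5% for the myogenic list, and an odds ratio of 0.1 was called in 45% for the known CREB1 target list and in 0% for the sarcomere, myogenic and clock lists. These simulations gave all genes outside the planted list the same chance of being CTRL-only, whatever their CTRL strength. They therefore do not show how often a list of unusual strength, such as the known CREB1 targets, would be called. Alternatives covered stricter q thresholds of 0.01 and 0.001, the same number of peaks from every library, each library left out, each replicate number alone, other overlap rules, gene-end windows of 500 and 3000 bp, the peak interval in place of the summit, and strata of CTRL strength. No file column belonged to samples outside the series.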

Results

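Binding of phosphorylated CREB1 was measured by ChIP-seq in muscle of control mice (CTRL) and of mice bearing C26 colon adenocarcinoma, a model of cancer cachexia. The series title places the comparison in the question of whether cAMP and CREB1 signaling is impaired in cachectic muscle, with mitochondrial function as the process of interest. Each group had 2 phospho-CREB1 libraries, and each library had its own list of peaks called against input. The lists held 10835 peaks (CTRL replicate 1), 14975 peaks (CTRL replicate 2), 7482 peaks (C26 replicate 1) and 4051 peaks (C26 replicate 2). They covered 5.90, 9.03, 3.64 and 1.88 Mb of the genome in the same order, with median peak widths of 481, 515, 433 and 420 bp. The median fold enrichment over input within a list, as the authors' peak caller gave it, was 6.43, 7.17, 5.55 and 6.98. Read depth per library is unknown, so the number of peaks in a list cannot be set against the number of reads behind it. All positions refer to mm10 (GRCm38).

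The first question was where phospho-CREB1 sat in muscle. Among gene-end peaks present in all 4 libraries, those at Psmb2, Rpl9 and Lias, Nup153, and Fancd2 and Emc3 were the strongest. Psmb2, a subunit of the 20S proteasome, carried a peak in CTRL replicate 2 at chromosome 4, 126677210 to 126678140, with 217-fold enrichment, and enrichments of 144-, 129- and 64.4-fold in CTRL replicate 1, C26 replicate 1 and C26 replicate 2. The peak at the shared end of Rpl9, a ribosomal protein gene, and Lias, lipoic acid synthetase (chromosome 5, 65391030 to 65392121), reached 218-fold in CTRL replicate 2 and was the strongest of C26 replicate 2 by −log10 q, at 76.9-fold. The others among the strongest shared gene-end peaks were at Nup153, a nuclear pore gene (chromosome 13, 46727497 to 46728336, 238-fold in CTRL replicate 2), and the shared end of Fancd2 and Emc3 (chromosome 6, 113531182 to 113532022, 134-fold in CTRL replicate 2). Enrichments from different lists were scaled separately by the authors and are not compared with each other.

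Genes known as direct CREB1 targets were among the occupied genes. Crem, which encodes a CREB1 relative with cAMP-induced repressor forms, had a peak at chromosome 18, 3336698 to 3338055 in CTRL replicate 2, with 79.5-fold enrichment there and 37.5-, 26.1- and 22.0-fold in CTRL replicate 1, C26 replicate 1 and C26 replicate 2. Sik1, a cAMP-induced kinase, had peaks of 42.7-, 37.5-, 30.4- and 13.8-fold in CTRL replicates 1 and 2 and C26 replicates 1 and 2, at chromosome 17, 31855331 to 31856495 in CTRL replicate 2. The immediate early gene Fos had peaks of 22.6-, 42.8-, 14.0- and 14.1-fold in the same order, at chromosome 12, 85473379 to 85474251 in CTRL replicate 2. The clock gene Per1 also had a peak in every library (26.8-, 30.1-, 15.5- and 13.2-fold, chromosome 11, 69094582 to 69095654 in CTRL replicate 2). Creb1 itself carried a peak in all 4 libraries (19.2-, 26.2-, 8.68- and 11.3-fold, chromosome 1, 64532203 to 64533530 in CTRL replicate 2).

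Across the 21883 protein-coding genes, 7035 (32.1%) had a gene-end peak in both CTRL libraries, and genes of energy metabolism and protein synthesis did so far more often. A peak in both CTRL libraries was found at 31 of 38 genes of OXPHOS complex I, the NADH dehydrogenase of the respiratory chain (81.6%, against 32.1% of other genes, odds ratio 9.38, adjusted p = 3.00e-09, Fisher's exact test). It was found at 29 of 32 genes of mitochondrial dynamics, import and quality control (90.6%, odds ratio 20.5, adjusted p = 7.60e-11) and at 68 of 82 cytosolic ribosomal protein genes (82.9%, odds ratio 10.3, adjusted p = 5.19e-20, Fisher's exact test). The fusion gene Mfn2 was an example, with 162.7-fold enrichment in CTRL replicate 2, as was the complex I gene Ndufa10, with 109.5-fold in the same list. The mitochondrial ribosome (50 of 75 genes), the TCA cycle and fatty acid oxidation (27 of 36), OXPHOS complexes II to V and cytochrome c (27 of 43), regulators of mitochondrial biogenesis (17 of 26), glycolysis and glycogen (18 of 29), the circadian clock (16 of 21), muscle atrophy and autophagy (29 of 41), inflammation and stress (16 of 30), cAMP and CREB signaling (21 of 44) and the known CREB1 targets (26 of 40) also had higher shares than other genes. Adjusted p-values for these lists ran from 4.93e-09 for the mitochondrial ribosome to 0.0412 for cAMP and CREB signaling (Fisher's exact test). In all, 13 of 19 lists were enriched. The comparison set was all other protein-coding genes, including families without such peaks, such as the olfactory receptors (0 of 1110). It was not limited to genes active in muscle, so a preference for these lists among active genes is not shown.

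Genes of the contractile apparatus and markers of other cell types did not follow this pattern. Of 40 sarcomere and contraction genes, 17 had a peak in both CTRL libraries (42.5%, odds ratio 1.56, adjusted p = 0.186, Fisher's exact test), and of 26 myogenic regulators 10 did (38.5%, odds ratio 1.32, p = 0.530). None of the 16 endothelial markers, 16 fibroblast and fibro-adipogenic markers or 20 leukocyte markers had a peak in both CTRL libraries, fewer than among other genes (32.2%), with adjusted p of 0.00347, 0.00347 and 9.55e-04. Kdr, Flt1, Fn1 and Col1a1 had a peak in CTRL replicate 2 alone, and no marker of these 3 lists had one in a C26 library. Among 12 adipocyte and Schwann cell markers, the share with a peak in both CTRL libraries was 8.33% (adjusted p = 0.133, Fisher's exact test).

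Summits clustered at gene ends in every library. Within 1000 bp of a gene end lay 60.2% of summits in CTRL replicate 1, 53.3% in CTRL replicate 2, 65.9% in C26 replicate 1 and 62.8% in C26 replicate 2, against 7.87% to 8.79% when the summits were moved by 10000 bp. A further 25.4%, 30.4%, 22.0% and 22.9% lay inside gene spans farther from the ends, and 14.4%, 16.3%, 12.2% and 14.3% lay outside genes. The mean share near gene ends was 56.8% ± 4.89 in CTRL and 64.3% ± 2.16 in C26 muscle (SD, n = 2 per group), a difference of 7.55 percentage points (exact permutation p = 0.333, the smallest this design allows).

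**Figure D1:**
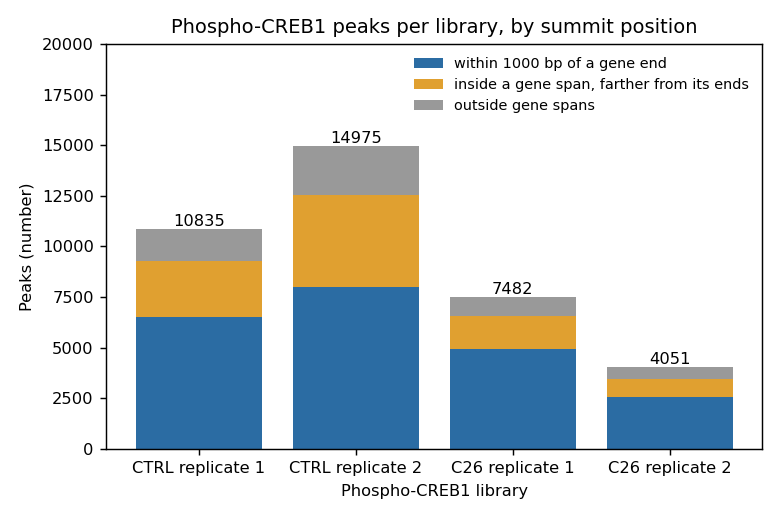
Number of phospho-CREB1 peaks (vertical axis) in each of the 4 libraries (horizontal axis), with bars divided by the position of the summit relative to protein-coding genes. The C26 lists hold 7482 and 4051 peaks and the CTRL lists 10835 and 14975, and the part within 1000 bp of a gene end is the largest in every library.

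The second question was whether phospho-CREB1 binding differed between CTRL and C26 muscle. Fewer peaks were called in both C26 libraries than in either CTRL library. The mean was 12905 ± 2927 peaks in CTRL and 5766 ± 2426 in C26 muscle (SD, n = 2 per group), a log2 ratio of −1.21 between the geometric means, or 2.31-fold more peaks in CTRL (exact permutation p = 0.333, two-sided, the smallest possible with 2 libraries against 2). The covered length was 7.46 ± 2.21 Mb in CTRL and 2.76 ± 1.24 Mb in C26 libraries (SD, n = 2 per group). The difference in peak number was larger than the spread within either group, but the test cannot pass a threshold of 0.05 at this size.

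The C26 peaks were in large part a subset of the CTRL peaks. The 4 lists merged into 17607 regions, of which 8972 were reproducible in CTRL and 3181 in C26 muscle. Of the reproducible C26 regions, 3115 (97.9%, 95% Wilson interval 97.4 to 98.4) had a peak in a CTRL library. In the other direction, 6211 of the reproducible CTRL regions (69.2%, 68.3 to 70.2) had a peak in a C26 library, compared with a mean of 0.646% and a maximum of 0.869% under random placement of the C26 peaks. The share was 65.8% in C26 replicate 1 and 36.6% in C26 replicate 2. Random placement did not keep the clustering of summits at gene ends, so that contrast includes any shared preference for gene ends. A peak was present in all 4 libraries at 2978 regions, of which 77.6% were near a gene end, a number that was 5902 without C26 replicate 2.

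CTRL-only regions far outnumbered C26-only regions. A peak in both CTRL libraries and neither C26 library was found at 2761 regions (30.8% of the reproducible CTRL regions, 29.8 to 31.7), and a peak in both C26 libraries and neither CTRL library at 66. The strongest CTRL-only regions away from gene ends lay inside Dnajb4, an HSP40 co-chaperone gene (chromosome 3, 152193544 to 152194131, 16.6- and 19.6-fold in CTRL replicates 1 and 2), and inside Mxi1, an antagonist of MYC (chromosome 19, 53329119 to 53330381, 13.7- and 18.1-fold). C26-only regions included a site inside Smad3, a transducer of TGF-β and myostatin signals (chromosome 9, 63745963 to 63746434, 6.81- and 8.24-fold in C26 replicates 1 and 2), and a site 31601 bp from Ppp1r3c, which encodes a glycogen-targeting subunit of protein phosphatase 1 (chromosome 19, 36767912 to 36768497, 7.82- and 8.25-fold). Only 3 of the 66 C26-only regions were near a gene end (4.55%, 1.56 to 12.5), compared with 1501 of the 2761 CTRL-only regions (54.4%, 52.5 to 56.2).

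The division of the regions between CTRL and C26 libraries was the largest of the 3 possible divisions of the 4 libraries into pairs. CTRL against C26 gave 2827 regions present in both libraries of one side and neither of the other, while replicates 1 against replicates 2 gave 327 and the crossed division gave 589. When each list was trimmed to its 4051 strongest peaks, the CTRL-only and C26-only regions numbered 267 and 178, a sum of 445 against 304 and 297 for the other divisions. The CTRL-only count also depended on which libraries were required: it was 7953 without CTRL replicate 1, 4348 without CTRL replicate 2 and 5686 without C26 replicate 1, and the C26-only count was 104, 163 and 393 without the same libraries and 631 without C26 replicate 2. The share of reproducible CTRL regions with a C26 peak was 36.6% without C26 replicate 1 and 91.7% with trimmed lists.

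**Figure D2:**
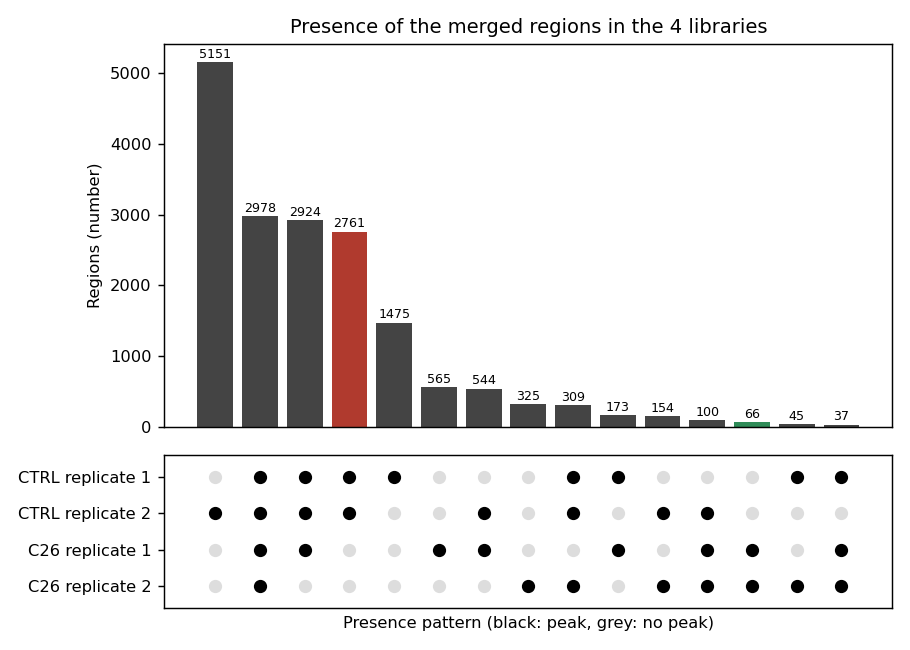
Number of merged regions (upper panel, vertical axis) for each pattern of presence in the 4 libraries (lower panel, black dots for a peak and grey dots for none). The 2761 CTRL-only regions (red) outnumber the 66 C26-only regions (green), and the most frequent pattern is a peak in CTRL replicate 2 alone (5151 regions).

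CTRL-only regions had weaker CTRL peaks than regions that were also bound in C26 muscle. Their median fold enrichment was 5.33 in CTRL replicate 1 and 7.03 in CTRL replicate 2, against 8.83 and 12.7 for regions with a peak in a C26 library and 12.8 and 18.0 for regions with a peak in both. In percentiles of peak strength, the CTRL-only regions had medians of 32.0 and 48.2 and the shared regions 70.3 and 78.5. Divided into deciles by the lower of the 2 CTRL percentiles, 71.6% of the regions in the weakest decile had no C26 peak (68.6 to 74.5), compared with 10.9% in decile 7, 0.223% in decile 9 and 0% of the 897 regions in the strongest decile (upper limit of the 95% Wilson interval, 0.426%). C26 replicate 1 had a peak at 23.1% of the weakest and 100% of the strongest decile, and C26 replicate 2 at 9.69% and 95.9%.

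**Figure D3:**
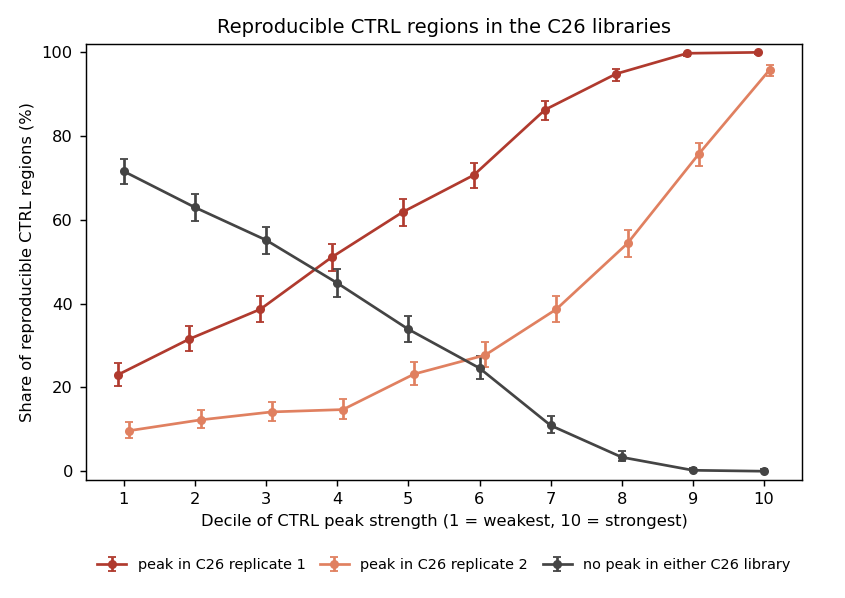
Share of the reproducible CTRL regions (vertical axis, %) with a peak in each C26 library or with no C26 peak, by decile of CTRL peak strength (horizontal axis, 1 for the weakest), with 95% Wilson intervals. The share without a C26 peak goes from 71.6% in the weakest decile to 0% in the strongest.

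CTRL-only regions were less frequent near gene ends than elsewhere. Summits of every library counted toward closeness to a gene end, so regions with a C26 peak had more summits to qualify. This favors odds ratios below 1 in the comparison that follows, by an amount that was not tested. Of 6128 reproducible CTRL regions near a gene end, 1501 (24.5%, 23.4 to 25.6) had no C26 peak, compared with 1260 of 2844 regions elsewhere (44.3%, 42.5 to 46.1; odds ratio 0.408, p = 1.85e-77, Fisher's exact test over regions). Regions near gene ends made up 46.4% of the weakest and 86.4% of the strongest decile of CTRL strength, and within deciles of strength the odds ratio was 0.782 (95% interval 0.699 to 0.875, exact Mantel-Haenszel p = 1.78e-05). This direction rested on C26 replicate 1: without that library the odds ratio was 1.44 (exact p = 1.31e-09), and with trimmed lists it was 0.976 (exact p = 0.867).

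At the level of genes, a gene-end peak was present in both CTRL and neither C26 library at 1619 of 7035 genes (23.0%) and in all 4 libraries at 2785 (39.6%). The strongest CTRL-only gene was Pdk1, a kinase that inhibits pyruvate dehydrogenase, with 14.7- and 17.1-fold enrichment in CTRL replicates 1 and 2 (chromosome 2, 71872927 to 71873727 in replicate 2, −log10 q 36.0). In order of strength, Nedd1, a centrosomal gene, came next with 11.7- and 14.2-fold enrichment (chromosome 10, 92721967 to 92722713). Taf10, a subunit of the general transcription factor TFIID that shares its peak with the lysosomal protease gene Tpp1, had 10.7- and 17.1-fold (chromosome 7, 105744174 to 105744699). They were followed by Nipsnap2, a mitochondrial protein gene (chromosome 5), Zbed6 and Zc3h11a, which share a peak (chromosome 1), the ribosome biogenesis gene Las1l (chromosome X), Zfp318 (chromosome 17), the histone chaperone gene Asf1a and Tspyl4 (chromosome 10). Asf1a had 10.2- and 21.2-fold enrichment (chromosome 10, 53596394 to 53597328). The others had 10.5- to 13.8-fold in CTRL replicate 1. Zbed6 encodes a repressor of the growth factor gene Igf2 in muscle.

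A gene-end peak in both C26 and neither CTRL library was found at 6 genes. For 3 of these, Ate1, Brd2 and Zzz3, a CTRL peak overlapped the C26 peak with its summit outside the window, at a distance that was not examined. Their C26 peaks therefore lay in merged regions that also had a CTRL peak. The others were Mt2, a metallothionein gene induced by glucocorticoids and zinc (C26 peaks of 4.03- and 7.16-fold, chromosome 8, 94174090 to 94174537 in C26 replicate 2), Commd9 (7.70- and 6.80-fold, chromosome 2, 101886082 to 101886360) and Rin2. The C26 peaks of Rin2 on chromosome 2 did not overlap. They were 4.33-fold at 145888260 to 145888769 in replicate 1 and 5.49-fold at 145887962 to 145888244 in replicate 2. The neighboring metallothionein gene Mt1 had a gene-end peak in all 4 libraries. Of the 1619 CTRL-only genes, 14 had an overlapping C26 peak outside the window. The gene counts followed the peak lists: CTRL-only genes numbered 3009 without CTRL replicate 1, 4102 without C26 replicate 1 and 233 with trimmed lists, and the C26-only genes numbered 13, 42, 30 and 75 without CTRL replicate 1, CTRL replicate 2, C26 replicate 1 and C26 replicate 2, and 84 with trimmed lists.

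Among the gene lists, CTRL-only peaks were found in every mitochondrial list, at shares of 17.2% to 23.5% of the occupied genes, and none of these lists passed the test. Of the 31 complex I genes with a peak in both CTRL libraries, 7 were CTRL-only (22.6%, 11.4 to 39.8, against 23.0% of other genes, adjusted p = 1.00, Fisher's exact test), 16 had a peak in 1 C26 library and 8 in both. The CTRL-only genes included Ndufs1, which encodes the largest complex I subunit (6.43- and 10.2-fold in CTRL replicates 1 and 2, peak shared with Eef1b2), Ndufb9 (7.60- and 15.9-fold, shared with Tatdn1) and Ndufb11 (7.36- and 7.34-fold, shared with Rbm10). In OXPHOS complexes II to V, 5 of 27 were CTRL-only, among them Cox7c (7.44- and 7.34-fold), a subunit of cytochrome c oxidase, and the ATP synthase genes Atp5j2 (6.78- and 10.9-fold) and Atp5l (5.21- and 7.34-fold). In the TCA cycle and fatty acid oxidation list, 5 of 27 were CTRL-only, among them Acadl (7.80- and 8.44-fold), Etfa (8.97- and 5.39-fold) and Cpt2, which releases fatty acids from carnitine inside mitochondria (4.55- and 11.9-fold).

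Mitochondrial maintenance and translation genes had similar proportions. In the list of dynamics, import and quality control, 5 of 29 were CTRL-only (17.2%, 7.60 to 34.5), with Mfn1, a fusion GTPase (7.58- and 8.44-fold in CTRL replicates 1 and 2), and the mitophagy genes Pink1 (6.09- and 8.92-fold) and Fundc1 (10.5- and 8.57-fold) among them. Of the biogenesis regulators, 4 of 17 were CTRL-only, including Ppara, a nuclear receptor of fatty acid oxidation (6.87- and 13.3-fold), Ppargc1b, a coactivator related to PGC-1α (7.53- and 7.96-fold), and Nfe2l2 (6.05- and 9.64-fold), which had an overlapping peak in C26 replicate 1 with its summit outside the window. In the mitochondrial ribosome, 10 of 50 were CTRL-only, among them Mrpl10, Mrpl21 and Mrps26, and in the cytosolic ribosome 11 of 68, among them Rps20, Rps15a and Rpl8 (7.11- to 7.97-fold in CTRL replicate 1). The adjusted p was 0.521 for the cytosolic ribosome and 1.00 for each mitochondrial list (Fisher's exact test). The odds ratio of the cytosolic ribosome was 0.643, and it ran from 0.427 to 0.645 with 1 library left out. For replicate numbers 1 and 2 alone it was 0.635 and 0.426.

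The known CREB1 targets were the 1 list that differed from other genes. None of their 26 occupied members was CTRL-only (0%, upper limit 12.9%), compared with 23.1% of other genes (odds ratio 0, p = 0.00172, adjusted p = 0.0275, Fisher's exact test). A peak was present in all 4 libraries at 22 of them, including Creb1, Crem, Sik1, Per1, Fos, Junb, Atf3, Nr4a2 and Irs2. The orphan nuclear receptor gene Nr4a3 had 17.1-, 22.9-, 6.53- and 8.92-fold enrichment in CTRL replicates 1 and 2 and C26 replicates 1 and 2 (chromosome 4, 48044251 to 48045324 in CTRL replicate 2). The remaining 4, Nr4a1 (20.3-, 14.5- and 7.76-fold in CTRL replicates 1 and 2 and C26 replicate 1, chromosome 15), Dusp1, Cited2 and Crebrf, had a C26 peak in replicate 1 only. Ppargc1a, which encodes the coactivator PGC-1α and is a CREB1 target in muscle and liver, had a gene-end peak in CTRL replicate 2 alone, and that was among the weakest of its list (3.91-fold, −log10 q 2.25, chromosome 5, 52115942 to 52116222). The window covered only the ends of the Ppargc1a span (51454249 to 52115853). Peaks at start sites farther inside a span were not counted, for this or any other gene, so binding there was not examined. The targets had stronger CTRL peaks than other genes, with a median lower percentile of 85.4 against 62.6, and the list no longer passed when genes of like strength were compared (adjusted p = 0.970 over 3 bins of strength, exact Mantel-Haenszel test), although the odds ratio stayed at 0. It also missed the threshold at q thresholds of 0.01 and 0.001 (odds ratios 0.131 and 0.125, adjusted p = 0.281 and 0.171), with trimmed lists (odds ratio 0, adjusted p = 1.00) and with a 500 bp window (odds ratio 0, adjusted p = 0.0738), all by Fisher's exact test.

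In lists tied to muscle mass and structure, no difference passed the adjusted threshold. Of 29 atrophy and autophagy genes with a peak in both CTRL libraries, 2 were CTRL-only (6.90%, 1.91 to 22.0, p = 0.0441, adjusted p = 0.304, Fisher's exact test): the autophagy kinase gene Ulk1 (5.41- and 8.45-fold in CTRL replicates 1 and 2) and the F-box gene Fbxo21 (5.98- and 5.68-fold). Without CTRL replicate 1 the list passed (odds ratio 0.263, adjusted p = 0.0330), as it did with a window of 3000 bp (odds ratio 0.106, adjusted p = 0.0292, Fisher's exact test). Over 3 bins of strength it did not (odds ratio 0.254 against 0.247 without them, adjusted p = 0.823, exact Mantel-Haenszel test). The ubiquitin ligase gene Fbxo32 (atrogin-1) had a peak in all 4 libraries (5.35-, 13.1-, 4.14- and 7.48-fold in CTRL replicates 1 and 2 and C26 replicates 1 and 2), and Trim63 (MuRF1) in CTRL replicate 2 (4.27-fold) and both C26 libraries (7.19- and 5.87-fold). Of 17 sarcomere and contraction genes, 7 were CTRL-only (41.2%, 21.6 to 64.0, odds ratio 2.35, p = 0.0852, adjusted p = 0.341, Fisher's exact test). Their CTRL peaks were weak, with a median lower percentile of 27.2, and over 3 bins of strength the odds ratio was 0.995 (adjusted p = 1.00, exact Mantel-Haenszel test). The CTRL-only genes included the calcium pump gene Atp2a1 (7.23- and 9.54-fold), Mybpc2 (5.07- and 5.38-fold, peak shared with Spib) and the calcium release channel gene Ryr1 (6.62- and 6.88-fold, in CTRL peaks that did not overlap), which had an overlapping peak in C26 replicate 1.

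Of 10 myogenic regulators, 5 were CTRL-only (interval of the share 23.7% to 76.3%, odds ratio 3.35, p = 0.0569, adjusted p = 0.304, Fisher's exact test): Nfix (13.3- and 12.0-fold in CTRL replicates 1 and 2), Prox1 (9.50- and 9.12-fold), Hdac5 (7.78- and 12.7-fold), Myod1 and Sox6. Over 3 bins of strength the odds ratio was 3.65 (adjusted p = 0.442, exact Mantel-Haenszel test). It was 1.64 and 3.98 without CTRL replicates 1 and 2, and 1.67 and 2.99 without C26 replicates 1 and 2. For replicate numbers 1 and 2 alone it was 3.58 and 1.18. A separate region 3823 bp from Myod1 had a peak in both replicate 2 libraries and in neither replicate 1 library. Nfix and Prox1 encode transcription factors of fiber maturation and fiber type. Of 18 glycolysis and glycogen genes, 3 were CTRL-only, namely Pygm, muscle glycogen phosphorylase (6.95- and 9.20-fold, in CTRL peaks that did not overlap), Pfkm (4.65- and 12.9-fold, shared with Senp1) and Phkb (4.20- and 5.81-fold, shared with Itfg1). Of 21 genes of cAMP and CREB signaling, 5 were CTRL-only, among them the coactivator gene Ep300 (9.14- and 15.9-fold), Akap13 and Rapgef3. Ep300 had overlapping peaks in both C26 libraries with summits outside the window (6.10-fold in replicate 1 and 12.2-fold in replicate 2). Of 16 inflammation and stress genes, Ddit4 (3.78- and 15.2-fold) and Hsf1 (3.69- and 5.34-fold, shared with Bop1) were CTRL-only, and in the clock list the CTRL-only share was 6.25% of 16 genes. Adjusted p-values were 0.453 for the clock list and 1.00 for the glycolysis, signaling, inflammation and adipocyte and Schwann cell lists. In total 16 lists were tested for CTRL-only peaks, of which 1 passed the adjusted threshold and 2 had an unadjusted p under 0.05.

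**Figure D4:**
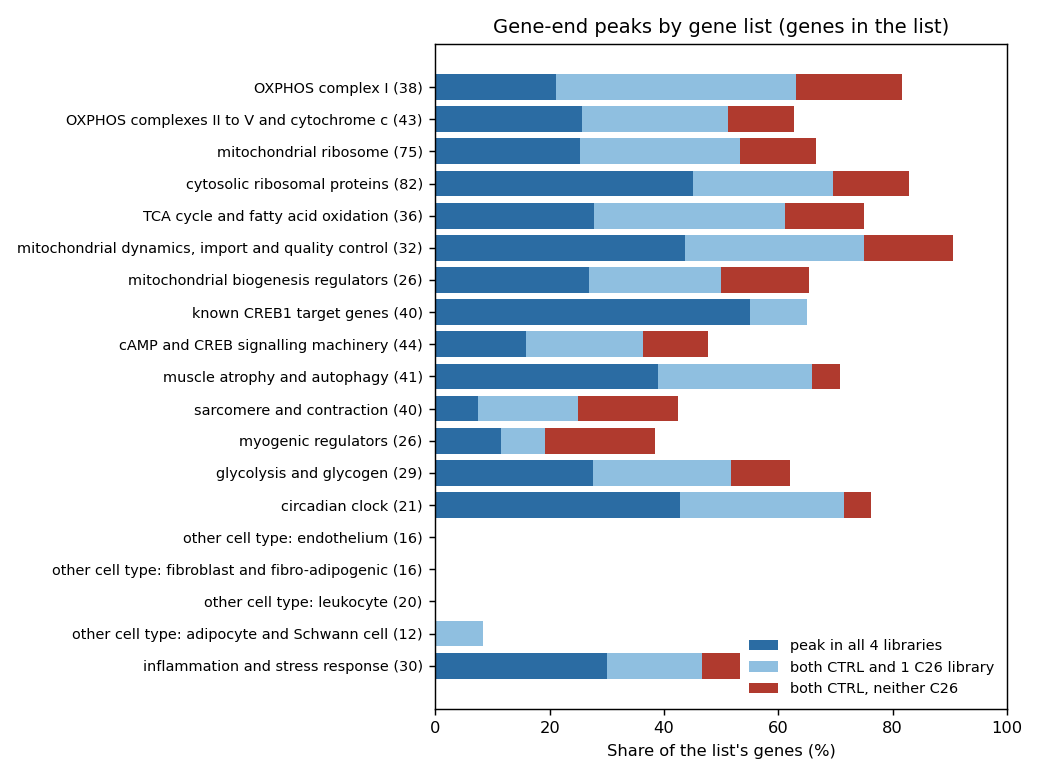
Share of each list's genes (horizontal axis, %) with a gene-end peak in both CTRL libraries, divided by presence in the C26 libraries, with the number of genes of each list in parentheses. The known CREB1 targets have no CTRL-only gene (red), and the endothelial, fibroblast and leukocyte markers have no bar because none has a peak in both CTRL libraries.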

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

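No test was run on the value given here, which was singled out by a rule set before the data were examined. C26 replicate 2 held 1 peak on the mitochondrial chromosome (M, 15590 to 16020), in the non-coding control region, with 2.20-fold enrichment over input and −log10 q of 49.4. It is counted among the 4051 peaks of that list and among the merged regions compared above. The other 3 libraries, both CTRL libraries among them, had 0 peaks on that chromosome. The enrichment of the peak was below the median of its own list (6.98), while its −log10 q was above that list's median (6.79).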

How the results depend on the processing

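The alternatives for the odds ratio near gene ends, for the number of lists with higher CTRL occupancy and with deciles of strength were chosen after the data were seen, and the rest before. Of 300 alternatives, 247 left the result on the same side of its test threshold, within 1.5 times its count or within its interval. A count or share moved farther in 41. A test that had passed no longer passed in 7, the opposite held in 4, and 1 reversed. List odds ratios made up 205 of the 300. A list that missed the threshold both times counted as unchanged, whichever side of 1 its odds ratio lay on. The log2 ratio of peak number stayed negative in all of its alternatives (−1.65 to −0.77). The number of lists with higher occupancy lay between 10 and 14 against 13. List odds ratios lay on the other side of 1 in 26 of 205 alternatives, none of them past the threshold, and 2 more for the adipocyte and Schwann cell list gave no finite value.

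With the same number of peaks from every library, CTRL-only regions numbered 267, C26-only regions 178, CTRL-only genes 233 and C26-only genes 84, the share of reproducible CTRL regions with a C26 peak was 91.7%, and the odds ratio near gene ends was 0.976 (exact p = 0.867), for which fewer regions and the loss of weak peaks are part of the construction. Leaving out 1 library at a time gave 3069 to 7953 CTRL-only regions, 104 to 631 C26-only regions, 3008 to 5902 regions in every library left, a share of 36.6% to 65.8%, 1767 to 4102 CTRL-only genes, 13 to 75 C26-only genes and 1 to 3 lists that passed, where a group reduced to 1 library needs only that library. The odds ratio near gene ends was 0.577 to 1.44, and the reversal to 1.44 came without C26 replicate 1 (exact p = 1.31e-09), the cause of which was not tested.

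When a peak had to cover 50% of the region, 1364 regions were in all 4 libraries and the share was 54.6%. With the peak interval in place of the summit, 2 genes were C26-only. The number of lists that passed was 0 at q of 0.01 and 0.001, with the same number of peaks, with a 500 bp window and over 3 bins or deciles of strength, and 2 with a 3000 bp window. The known CREB1 targets had an odds ratio of 0.131 at q of 0.01 (adjusted p = 0.281) and 0.125 at q of 0.001 (adjusted p = 0.171), and of 0 with the same number of peaks (adjusted p = 1.00), a 500 bp window (0.0738), 3 bins (0.970) and deciles of strength (1.00), and over all alternatives the adjusted p of the exact tests ran from 1.18e-05 to 1.00. The cause was not tested except for strength. Cytosolic ribosomal proteins passed without CTRL replicate 1 (odds ratio 0.427, adjusted p = 0.0330, Fisher's exact test) and atrophy and autophagy genes without CTRL replicate 1 (0.263) and with a 3000 bp window (0.106).

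Whether the replicate numbers tie libraries together could not be decided with 2 pairs: over regions, the difference between CTRL replicates and that between C26 replicates had a correlation of 0.101, and CTRL had 1.45 times the peaks of C26 muscle for number 1 and 3.70 times for number 2. With the replicate number as a block, the log2 ratio was −1.21 (exact sign-flip p = 0.5, the smallest possible), the mean counts within a number were 7985 CTRL-only, 874 C26-only and 4826 shared regions, a share of 40.4%, 3926 CTRL-only and 212.5 C26-only genes, and for number 2 alone 2 lists passed, the second being the cytosolic ribosomal proteins (0.426). The cAMP response element search and its alternatives were not run, and trimming to equal numbers gives no ratio of peak numbers. Without read depth, differences among weak peaks are the least certain.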

Other observations

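The tests on gene families and on strong regions of CTRL replicate 2 were chosen after the data were seen, as were the families and regions named here, while the other tests were fixed before their results were seen. Families were formed by the stem of the gene symbol. Of 154 stems with at least 15 genes, 50 had more genes with a gene-end peak in both CTRL libraries than the rest of the genome and 49 had fewer, past an adjusted p of 0.05 (Fisher's exact test over genes). Examples of the former were the RNA polymerase subunits (Polr, 25 of 28 genes, odds ratio 17.7, adjusted p = 9.69e-09), the inner membrane import genes (Timm, 13 of 15, adjusted p = 1.11e-04), the autophagy genes (Atg, 15 of 18, adjusted p = 6.88e-05) and the translation initiation factors (Eif, 42 of 56, adjusted p = 1.74e-09), all by Fisher's exact test. Examples of the latter, not all of them the lowest, were the olfactory receptors (Olfr, 0 of 1110, adjusted p = 3.27e-191), the vomeronasal receptors (Vmn, 1 of 355) and the cytochrome P450 genes (Cyp, 6 of 99, adjusted p = 9.43e-09), by the same exact test. For CTRL-only peaks, none of 78 stems passed the adjusted threshold by Fisher's exact test, and 2 had an unadjusted p under 0.05, Eif (4 of 42 CTRL-only) and Rps (2 of 29).

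Peaks outside the gene-end window included some of the strongest of the data. A region 23231 bp from Chchd4, which encodes a receptor of the mitochondrial intermembrane space import pathway, had 138.0-, 169.8-, 88.6- and 74.4-fold enrichment in CTRL replicates 1 and 2 and C26 replicates 1 and 2 (chromosome 6, 91440370 to 91441719). Regions inside Esyt2 (chromosome 12, 116280441 to 116281907), Eprs (chromosome 1, 185362478 to 185364083) and Supv3l1 (chromosome 10, 62449207 to 62450485) followed. Supv3l1 encodes a mitochondrial RNA helicase. Their enrichments were 117-, 97.4- and 78.7-fold in CTRL replicate 1, in that order. These regions lay 1891, 1864 and 1669 bp from an end of the same gene, much closer to a gene end than the Chchd4 region. Whether they sat at a transcript start was not tested, because transcript starts were not given.

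Peaks at or near 3 genes that govern the making of muscle cells were strong in CTRL replicate 2 and present in the replicate 2 libraries only. Of 1498 regions in the strongest decile of CTRL replicate 2, 3 had no peak in CTRL replicate 1, and these lay at Myog (chromosome 1, 134289640 to 134291645, over the gene's end, 94.0-fold), 3823 bp from Myod1 (chromosome 7, 46370973 to 46372986, 64.2-fold) and inside Pax7 (chromosome 4, 139770807 to 139772067, 41.4-fold). All 3 also had a peak in C26 replicate 2 (9.88-, 6.46- and 4.95-fold, percentiles 75.4, 43.5 and 17.5 of that list) and none had a peak in C26 replicate 1, while 0 of 1085 regions in the strongest decile of CTRL replicate 1 lacked a peak in CTRL replicate 2. The 3 regions were all nearest to a gene of the fixed myogenic list, compared with 6 of all 1498 (p = 3.58e-08, Fisher's exact test). This test was chosen after the regions were seen at these genes, so it restates the pattern. It cannot decide whether lower sensitivity of CTRL replicate 1 left the regions without a peak there. The strength of the regions did not decide it either (mean percentile 97.8 in CTRL replicate 2, exact rank-sum p = 0.0934 against the other 1495 regions). For C26 replicate 1, other regions in the same deciles of C26 replicate 2 strength had a peak in 96.3%, 81.3% and 54.0% of cases for Myog, Myod1 and Pax7. The product of the shares without a peak was 0.00323, taking the regions as independent. That comparison cannot decide the question, because the other regions were not chosen for lacking a CTRL replicate 1 peak. Regions with peaks in both replicate 2 libraries and not in CTRL replicate 1 were counted at any strength. Of these, 154 lacked a C26 replicate 1 peak and 100 had one. The 489 other CTRL replicate 2 regions at least as strong as the Pax7 region all had a C26 replicate 1 peak. All of them also had a CTRL replicate 1 peak. Lower sensitivity of C26 replicate 1 therefore stays open. What also stays open are DNA from these loci in the replicate 2 preparations that did not come from the precipitation, such as an amplified product or a construct, and a difference between the animals or muscle pieces of the 2 numbers, and no biological explanation was tested because input signal was not analysed here.

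The excess of CTRL-only regions may come in part from the longer CTRL lists. With the same number of peaks from every library, CTRL against C26 gave 1.46 times the regions of the higher of the other 2 divisions (445 against 304), down from 4.80 times with the full lists, and 3 divisions are too few for a share under 0.05. Lower sensitivity of the C26 libraries was tested by asking whether, within deciles of CTRL replicate 2 strength, a missing peak depended on closeness to a gene end as it did for CTRL replicate 1 (odds ratio 0.591, 0.540 to 0.647). C26 replicate 1 gave 0.686 (0.625 to 0.752), which overlaps, and C26 replicate 2 gave 1.43 (1.28 to 1.59), which lies on the other side of 1, so that the mean C26 odds ratio was 1.68 times that of CTRL replicate 1 and the C26 libraries did not behave alike. Here too, summits of every library counted toward closeness to a gene end, the tested library included. This favors odds ratios below 1 by an amount that was not tested and may differ between the libraries. Lower sensitivity and less phospho-CREB1 binding in C26 muscle therefore cannot be told apart without read depth, and the tumor stays open as an untested cause.

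The absence of CTRL-only peaks among known CREB1 targets is a pattern that their strong CTRL peaks could account for. At the overall share, 5.98 of the 26 genes were expected to be CTRL-only, and at the shares of their deciles of CTRL strength 1.04, against 0 observed. Over deciles of strength the odds ratio stayed at 0 and the exact Mantel-Haenszel p was 0.596. With so few expected, no shortage beyond strength was detectable, and the lost call alone does not show that strength was the cause. A retention of binding at these genes for another reason was not excluded.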
